A study of Mus musculus with 12 samples.

How the data were processed

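RNA was sequenced from L4-6 sciatic dorsal root ganglion neurons of 8-week C57BL/6J mice, 72 h after spinal cord injury, in 4 groups of 3 libraries. The AAV experiment held AAV-GFP and AAV-TKT, with the virus given 4 weeks earlier through the sciatic nerve, and the ribose experiment held Vehicle and 10% ribose. Per the labels' protocols, polyadenylated RNA was extracted with a micro-scale column kit and made into stranded libraries. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20, checked with FastQC, trimmed with Trim Galore and referred to GRCm38. The aligner, the read counter, the annotation release and the normalization of the column totals are not given in the sources used here.

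The deposited values are FPKM, which the authors computed for 1 table per experiment. The AAV table listed 13178 genes, every one with a mean of at least 1 FPKM over its 6 libraries (lowest mean 1.00041), so it appears to have been filtered before deposition. The ribose table listed 21650 genes and kept low values. Because the 2 tables were filtered differently and their normalization is not stated, levels were never compared across them, only differences within each. Gene identifiers were matched to GENCODE M21, which gave a symbol to 13170 of 13178 and 21612 of 21650. Pearson correlations between libraries on the log2 scale were 0.9717 to 0.9854 in the AAV table and 0.9244 to 0.9664 in the ribose table. The non-coding RNA Rn7s2 took between 6.32% and 12.6% of the FPKM total of each AAV library, and between 18.7% and 26.7% in the ribose experiment. Depth was not stated. Relative depths were read from the spacing of the lowest values where these fitted every pair of libraries, which held in the ribose table (largest residual 0.0162 on the natural log scale) and not in the AAV table (0.304). Nothing in the sources says that the 3 replicates of a group came from separate animals, and if they did not, the p-values measure only the spread between these samples.

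Groups were compared within each experiment on log2(FPKM + 1) for genes with a mean of at least 1 FPKM, using limma 3.58.1 in R 4.3.3 with an intensity trend in the variance prior and a Benjamini-Hochberg threshold of 0.05. An exact permutation test over the libraries was added for Tkt. The difference between the 2 effects was tested in limma over the genes of both tables. The groups shared 1 estimate of the spread per gene, although libraries correlated less in the ribose experiment. The p-values of a difference may therefore be too small where the ribose libraries varied more. The correlation of the effects was set against 400 joint relabellings. The 45 gene lists, their members, the tests and the rule for naming genes were fixed before the data were examined. Lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it. Values were also tested on simulated data with known changes. The AAV layout called 83% of 2-fold and 96.5% of 4-fold changes, and the ribose layout 32% and 69.5%. False calls averaged 14.5 of 194 and 5 of 106.5 calls. The simulation drew noise independently for each gene and changed many genes at once, which loosens the threshold. Its rates therefore do not carry over to the real libraries, where 2 and 1 genes passed. In the AAV experiment, for example, 0 of 11 neutrophil markers passed over all genes at a median log2 change of -2.12. A gene that was not called cannot be taken as unchanged.

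Named genes were Tkt and every measured member of the pentose phosphate pathway list, then per direction up to 10 genes past the threshold and separated between the groups. Genes with provisional names were left out. Remaining places went to separated genes with the smallest unadjusted p and a log2 change of at least 0.5 in size, given as values and not as changes. Added to these were the 4 members with the smallest p of each list past the threshold, up to 2 of other lists, and 5 genes per sign for the difference. A few list members that this rule names are not reported here. Gm24895, Gm15387 and Gm4332 fall outside this rule.

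Alternatives tried were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 FPKM, equal totals, median-of-ratios scaling, quantile normalization, the replicate number as a block, weights per library, a robust prior and each library left out in turn. Protein-coding genes alone, removal of the trend with gene length (loess, span 0.3), both together, and the joint omission of Vehicle replicate 2 and Ribose replicate 2 were added after seeing the data. Processed pseudogenes were matched to protein-coding transcripts by shared 31-base words, with at least 20% of words shared. One more test was run after the values were seen and was then taken out of the set of weighed tests to keep to 3 patterns. It asked whether Ribose replicate 2 lay below both other Ribose libraries in 6 non-neuronal lists. It did in 6 of 6, and of these scores only those of satellite glia are written out below. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and figures. No sample was left out of the reported comparisons.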

Results

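The series profiled mouse dorsal root ganglia, the clusters of sensory neurons beside the spinal cord that send one axon branch to the periphery and another into the cord. Ganglion neurons of the L4-6 levels, which feed the sciatic nerve, were collected 72 h after spinal cord injury from 8-week C57BL/6J mice. The libraries also held transcripts of glia, fibroblasts and blood cells. A difference can therefore come from the mix of cells as well as from within neurons. In the AAV experiment, an adeno-associated virus had been injected into the sciatic nerve for 4 weeks, and it carried either green fluorescent protein (AAV-GFP) or transketolase (AAV-TKT). Transketolase, encoded by Tkt, is an enzyme of the non-oxidative branch of the pentose phosphate pathway. That pathway links glucose breakdown to ribose and NADPH supply. In the ribose experiment, mice were treated with vehicle or 10% ribose, a pentose sugar that can enter the same pathway. Each of the 4 groups held 3 libraries. The AAV table listed 13178 genes, all with a mean of at least 1 FPKM (fragments per kilobase of transcript, scaled to library size), with totals of 413635 to 456084 FPKM per library. The ribose table listed 21650 genes, of which 13804 reached a mean of 1 FPKM, with totals of 510551 to 551370 FPKM per library. Read counts were not part of these tables, so the depth is unknown in the AAV libraries. Low values in the ribose table fell in steps that gave relative depths of 1.01, 1.24 and 1.34 for the Vehicle libraries and 0.754, 0.905 and 0.877 for the Ribose libraries. Genes listed at 0 made up 8.24% ± 2.63 (SD, n = 3) of the Vehicle lists and 13.3% ± 1.59 (SD, n = 3) of the Ribose lists.

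The AAV experiment asked what raising transketolase does to the transcripts of the ganglia after a spinal cord injury. Tkt rose 2.43-fold, from 102.1 ± 4.18 FPKM in AAV-GFP to 248 ± 21.9 FPKM in AAV-TKT (SD, n = 3 each). As lists, neutrophil, red-cell and macrophage markers were lower in AAV-TKT, and among them Ngp, a neutrophil granule protein, and Lyz2, the lysozyme of myeloid cells, had the smallest p without passing. All libraries of the groups were separated for 11 of 11 neutrophil, 7 of 9 red-cell and 7 of 12 macrophage markers, and 1 marker each of the last pair of lists was positive. Regeneration-associated genes and markers of non-peptidergic nociceptors, the small unmyelinated pain and itch neurons, were lower, while genes of the respiratory chain and markers of large-diameter neurons were slightly higher, again as lists. Apart from Tkt, the only gene past the threshold over all genes was Gm24895, a small nucleolar RNA, and every list call was lost when the correlation between genes was estimated from these libraries.

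Tkt (ENSMUSG00000021957) lies on chromosome 14, from 30548359 to 30574720 on the plus strand of GRCm38, and its FPKM summarises its exons. The microRNA gene Mir3076 overlaps this span on the same strand, and whether it falls in an exon of Tkt was not examined. The log2(FPKM + 1) change of Tkt was 1.27 (SE 0.0843, limma adjusted p = 0.0054), and every AAV-TKT library lay above every AAV-GFP library. The exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. Reads from the virus that match Tkt cannot be told from reads of the mouse gene in these values. Across single left-out libraries the change stayed between 1.23 and 1.34, with adjusted p between 0.0102 and 0.0475.

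**Figure D1:**
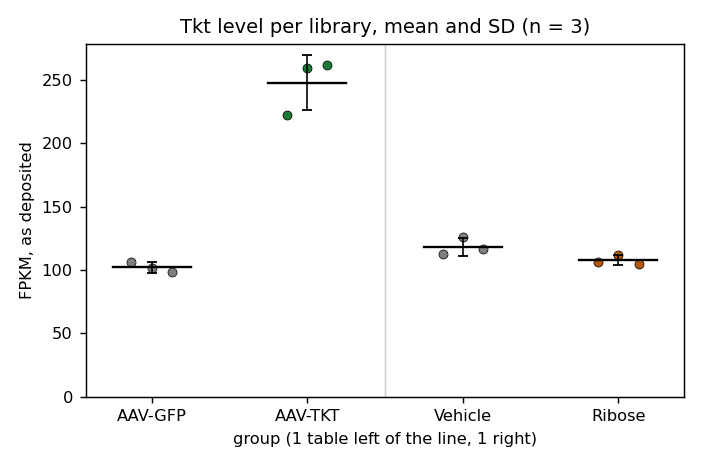
Tkt level in FPKM, as deposited (vertical axis), for each library (points) of the 4 groups, with the mean and SD of 3 libraries. The AAV-TKT libraries averaged 248 FPKM and the AAV-GFP libraries 102.1 FPKM, while Vehicle and Ribose averaged 118 and 108 FPKM. Levels are not compared between the experiments, since how their tables were normalized is not stated.

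The other measured members of the pentose phosphate pathway list did not pass the test in AAV-TKT. The enzymes of the oxidative branch kept similar levels, with G6pdx, the entry dehydrogenase, at 23.3 ± 1.34 and 22.98 ± 2.58 FPKM in AAV-GFP and AAV-TKT, Pgls, the lactonase, at 16.3 ± 1.68 and 17.1 ± 0.518 FPKM, and Pgd, the second dehydrogenase, at 27.9 ± 1.08 and 29.8 ± 1.94 FPKM. In the non-oxidative branch, the transaldolase Taldo1 was at 69.9 ± 4.62 and 76.7 ± 6.61 FPKM, the isomerase Rpia at 3.25 ± 0.570 and 2.74 ± 0.301 FPKM, and the epimerase Rpe at 16.5 ± 0.627 and 17.2 ± 1.49 FPKM. Log2 changes were 0.02 for H6pd, the endoplasmic reticulum counterpart of the first steps, 0.24 for the ribokinase Rbks, 0.01 for both Prps1 and Prps2, which make the activated ribose of nucleotide synthesis, and -0.03 for the sedoheptulose kinase Shpk. As a list of 12 measured genes the pathway had a median log2 change of 0.040 (camera adjusted p = 0.120). Tkt was its only call both over all genes and adjusted over the list alone.

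Energy metabolism lists moved by small amounts in AAV-TKT. The 71 nuclear genes of oxidative phosphorylation had a median log2 change of 0.14, with 62 of them positive (camera adjusted p = 3.4e-06). With an estimated correlation the adjusted p = 0.623. Ndufa13 (0.33), Ndufs7 (0.25) and Ndufb10 (0.30), subunits of complex I, and Cox6a1 (0.36), of cytochrome c oxidase, had the smallest p, and each was higher in all 3 AAV-TKT libraries, with adjusted p between 0.284 and 0.378. The list scores of the groups overlapped. AAV-TKT replicate 2 had the highest score (0.14), as it did for the tricarboxylic acid cycle, mitochondrial ribosomal and proteasome lists (0.10, 0.15 and 0.20), and it was lowest in satellite glia, fibroblast and Schwann cell scores. Without it the oxidative phosphorylation median was 0.084. With equal totals per library the list median was 0.067, while the median of all genes also moved, from 0.014 to -0.048. The tricarboxylic acid cycle list had a median of 0.12 (adjusted p = 0.00319, and adjusted p = 0.628 with an estimated correlation), with Pdhb of pyruvate dehydrogenase and the dehydrogenases Mdh2 and Sdhb at 0.21, 0.21 and 0.18. Mitochondrial ribosomal proteins (median 0.086, adjusted p = 0.0106, and adjusted p = 0.760 with an estimated correlation) were led by Mrpl37, Mrpl2, Mrps14 and Mrps26 (0.25, 0.28, 0.25 and 0.17). Fatty acid oxidation (median 0.087, adjusted p = 0.0167, and adjusted p = 0.499 with an estimated correlation) was led by the isomerase Eci1 (0.26) and the acyl-CoA dehydrogenase Acadvl (0.20), with the electron transfer flavoprotein genes Etfb and Etfa at 0.28 and 0.17. The 13 genes encoded by the mitochondrial genome moved the other way (median -0.35, adjusted p = 0.0126, and adjusted p = 0.681 with an estimated correlation), with mt-Co1 of cytochrome c oxidase at -0.62, mt-Nd1 and mt-Nd2 of complex I at -0.45 and -0.43, and mt-Cytb at -0.41. No gene of these 5 lists passed the threshold over all genes or adjusted over the list alone. The mitochondrially encoded share of FPKM outside the abundant Rn7s2 differed by library, from 0.635% in AAV-TKT replicate 2 to 2.03% in AAV-GFP replicate 3. Without the former the median of this list was 0.029 (adjusted p = 0.960), and without the latter it was -0.11 (adjusted p = 0.436). With all libraries kept, the mitochondrially encoded list also lost its call with equal totals (median -0.42, adjusted p = 0.0899) and with weights per library (median -0.15, adjusted p = 0.332). The tricarboxylic acid cycle and fatty acid oxidation lists lost their calls without AAV-GFP replicate 3 (medians 0.047 and 0.042) or AAV-TKT replicate 2 (adjusted p up to 0.0943 and 0.132), and mitochondrial ribosomal proteins lost theirs without either of these, AAV-GFP replicate 2 or AAV-TKT replicate 3 (up to 0.657), with a median of 0.031 without AAV-TKT replicate 2 and 0.15 without AAV-TKT replicate 1.

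Neutrophil and red-cell markers had the largest median differences among the 41 lists tested in the AAV experiment. All 11 measured neutrophil markers were lower in every AAV-TKT library than in every AAV-GFP library, with a median log2 change of -2.12 (camera adjusted p = 1.8e-18). With an estimated correlation the adjusted p = 0.449. Ngp went from 46.2 ± 17.3 to 6.40 ± 1.74 FPKM, the iron-binding lactotransferrin Ltf from 15.7 ± 6.46 to 2.25 ± 0.305, the lipocalin Lcn2 from 13.6 ± 5.77 to 1.88 ± 0.453, and the calprotectin subunit S100a9 from 41.8 ± 22.98 to 5.82 ± 1.05 FPKM (SD, n = 3 each). None passed over all genes, and 11 passed when adjusted over the list alone. Red-cell markers (9 measured, median -1.57, adjusted p = 1.1e-05, and adjusted p = 0.449 with an estimated correlation) included the globin genes Hba-a2 (125 ± 69.0 to 33.0 ± 4.49 FPKM), Hba-a1 (72.4 ± 41.7 to 17.2 ± 3.01) and Hbb-bt (23.6 ± 16.2 to 4.25 ± 0.997), and Alas2, the first enzyme of red-cell heme synthesis (2.13 ± 1.26 to 0.394 ± 0.195). Of these markers 6 passed adjusted over the list alone and 0 over all genes. Among 12 macrophage markers (median -0.62, adjusted p = 1.8e-09, and adjusted p = 0.449 with an estimated correlation), 7 passed adjusted over the list alone and 0 over all genes. Lyz2 was at 29.3 ± 5.60 and 9.34 ± 1.41 FPKM, the Fc receptor chain Fcer1g at 2.35 ± 0.761 and 0.569 ± 0.1002, the endotoxin co-receptor Cd14 at 1.87 ± 0.229 and 0.693 ± 0.232, and the leukocyte phosphatase Ptprc at 1.98 ± 0.387 and 0.814 ± 0.254. Lyz2 is a gene of myeloid cells and Ptprc of leukocytes, so their fall cannot be set apart from that of the neutrophil markers.

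Inflammatory and early-response lists were lower as well. The 10 measured cytokine and NF-kB target genes were all negative (median -0.26, camera adjusted p = 3.4e-05, and adjusted p = 0.380 with an estimated correlation). It was the only list past the threshold in fry, which asks whether the genes of a list move one way on balance (adjusted p = 0.0027). Il1b, the interleukin of activated myeloid cells, was at 2.94 ± 0.427 and 0.778 ± 0.218 FPKM, and the NF-kB inhibitors Tnfaip3 and Nfkbia had log2 changes of -0.62 and -0.37. These 3 passed adjusted over the list alone and 0 passed over all genes. The adhesion molecule Vcam1 was at -0.42. Complement genes (median -0.34, adjusted p = 7.1e-05, and adjusted p = 0.449 with an estimated correlation) included C3 (-0.95) and C1qc (-0.61), its 2 calls adjusted over the list alone, with the inhibitor Serping1 at -0.33 and C4b at -0.49. Of the 9 measured complement genes, 3 (C1qa, C1qb and C1qc) are also in the macrophage list, as is Ccl2 of the cytokine list, so these lists are not separate evidence. Il1b, as a gene of myeloid cells, may also follow the fall of the neutrophil markers, which was not tested. Immediate early genes, which respond within minutes to activity or tissue handling, had a median of -0.32 (adjusted p = 7.9e-08, and adjusted p = 0.499 with an estimated correlation), with Dusp6, a MAP kinase phosphatase, at -0.46, Klf2 and Klf4 at -0.53 and -0.51, and Egr1 at -0.62. Their list scores overlapped between the groups, AAV-TKT replicate 2 being lowest (-0.43), and the median was -0.18 without it and -0.55 without AAV-TKT replicate 1. Atf3 and Jun of this list are also in the regeneration list. Antigen presentation genes (median -0.14, adjusted p = 0.0451, and adjusted p = 0.640 with an estimated correlation) held 2 calls adjusted over the list alone in opposite directions, Tapbp (0.27) and H2-Q4 (-0.50), with H2-DMa at 0.28 and H2-Eb1 at -0.29. This list lost its call without AAV-GFP replicate 2 or 3 or AAV-TKT replicate 1 or 3 (adjusted p up to 0.342). It passed in 9 of 13 other settings, and was lost with equal totals, median-of-ratios scaling, quantile normalization and weights per library (up to 0.0769). Cell cycle genes had a median of -0.098 (adjusted p = 0.0104, and adjusted p = 0.449 with an estimated correlation), with the ribonucleotide reductase subunit Rrm2 (-0.80) its only call adjusted over the list alone, the proliferation marker Mki67 at -0.91, Tyms at -0.38 and Pcna at -0.18. This call was lost without AAV-GFP replicate 1 or 3 or AAV-TKT replicate 3 (up to 0.111), and the list median was -0.18 without AAV-TKT replicate 2. It was also lost with quantile normalization (median -0.011, adjusted p = 0.0575).

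**Figure D2:**
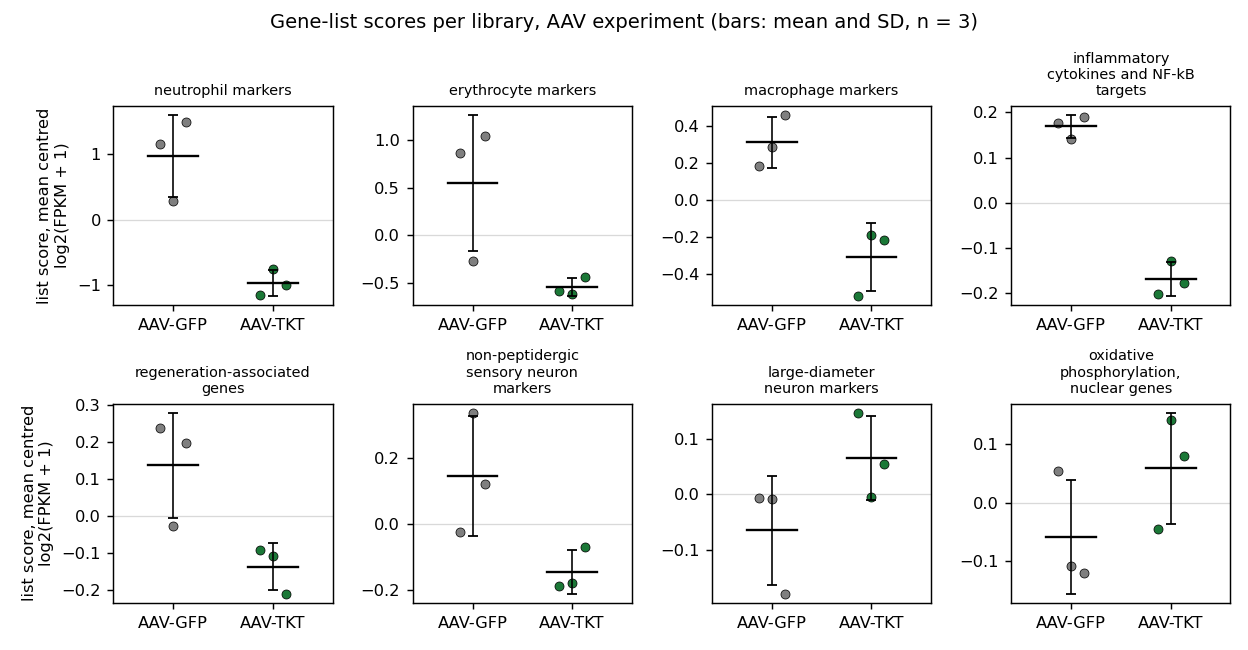
List scores, the mean over a list's measured genes of the centred log2(FPKM + 1) (vertical axes, each with its own range), for each library (points) of AAV-GFP and AAV-TKT, with the mean and SD of 3 libraries. Neutrophil scores averaged 0.97 in AAV-GFP and -0.97 in AAV-TKT, and AAV-GFP replicate 2, the middle point, lay nearest to the AAV-TKT libraries in the neutrophil and erythrocyte panels.

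In the regeneration list, 25 of 30 regeneration-associated genes were negative (median -0.14, camera adjusted p = 8.6e-06, and adjusted p = 0.449 with an estimated correlation). Plaur, the urokinase receptor (-0.76), Nts, the neuropeptide neurotensin (-1.08), Flrt3, a guidance-related membrane protein (-0.46), and Anxa1, an annexin (-1.38), passed adjusted over the list alone, as did the heat shock protein gene Hspb1 in the other direction (0.34), whereas 0 passed over all genes. Blood markers moved with this list between libraries of AAV-GFP, where replicates 1, 2 and 3 had regeneration scores of 0.24, -0.026 and 0.20, neutrophil scores of 1.15, 0.28 and 1.48 and erythrocyte scores of 0.87, -0.27 and 1.05. All 16 markers of non-peptidergic nociceptors were negative (median -0.25, adjusted p = 2.1e-07, and adjusted p = 0.449 with an estimated correlation). The lysophosphatidic acid receptors Lpar5 and Lpar3 were at -0.45 and -0.43, the itch cytokine receptor Il31ra at -0.52 and the leukotriene receptor Cysltr2 at -0.42. Lpar5 and Il31ra passed adjusted over the list alone. Markers of large-diameter neurons, the touch and position sensors, had a median of 0.12 (adjusted p = 0.00186, and adjusted p = 0.623 with an estimated correlation). Their 4 calls adjusted over the list alone were the calcium buffer Pvalb (34.6 ± 3.77 to 47.8 ± 4.31 FPKM), the vesicular glutamate transporter Slc17a7 (76.2 ± 3.53 to 95.9 ± 8.53), the acid-sensing channel Asic1 (40.7 ± 1.21 to 49.9 ± 4.42) and the heavy neurofilament Nefh (658 ± 33.1 to 819 ± 47.9). Axon growth and cytoskeleton genes (median 0.10, adjusted p = 0.0126, and adjusted p = 0.648 with an estimated correlation) included Nefh, the light neurofilament Nefl (0.29), Stmn3, a tubulin-binding protein (0.31), and Marcks (-0.20). Pan-neuronal genes (median 0.071, adjusted p = 0.0252, and adjusted p = 0.599 with an estimated correlation) included the splicing factor Rbfox3 (0.28), the neuronal enolase Eno2 (0.24) and Syt1 (-0.30). Without AAV-GFP replicate 3 the large-diameter and axon growth lists lost their calls (medians 0.051 and 0.046, adjusted p = 0.0694 and 0.142), and pan-neuronal genes lost theirs without AAV-GFP replicate 1 or 3 or AAV-TKT replicate 2 (up to 0.0943). Medians also moved without AAV-GFP replicate 2, to -0.23 for regeneration-associated, 0.18 for large-diameter and 0.12 for pan-neuronal genes, and without AAV-GFP replicate 1, to -0.39 for non-peptidergic markers. With weights per library the non-peptidergic median was -0.12.

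Glial and stromal markers were lower as lists, and AAV-TKT replicate 2 stood apart from the other AAV-TKT libraries in them. Its scores were -0.56 for satellite glia (others 0.21 and 0.00049), -0.46 for fibroblast (0.037 and -0.13) and -0.34 for Schwann cell markers (0.025 and -0.056), and without it the medians were -0.048, -0.25 and -0.15. Schwann cell and myelin genes had a median log2 change of -0.24 (camera adjusted p = 7.9e-05, and adjusted p = 0.449 with an estimated correlation), with the myelin proteins Mal at -0.48 and Mbp at -0.32, and the claudin Cldn19 at -0.45. Fibroblast and matrix genes (median -0.42, adjusted p = 9.2e-05, and adjusted p = 0.449 with an estimated correlation) included fibronectin Fn1 (-0.79), Igfbp5 (-0.44), the collagen Col3a1 (-0.52) and Apod (-0.67). Satellite glia markers (median -0.30, adjusted p = 0.0106, and adjusted p = 0.681 with an estimated correlation) held S100b in the opposite direction (0.32), with Sostdc1 at -0.37 and the glutamate transporter Slc1a3 at -0.42. That list lost its call without AAV-GFP replicate 1 or AAV-TKT replicate 2 (adjusted p up to 0.960), and its median was -0.52 without AAV-TKT replicate 1, while the Schwann cell median was -0.37 without AAV-GFP replicate 2. In these 3 lists 0 genes passed over all genes or adjusted over the list alone. Proteasome subunits (median 0.13, adjusted p = 1.2e-04, and adjusted p = 0.628 with an estimated correlation) were led by Psmd2, Psmc5, Psmb4 and Psmb6 (0.22, 0.22, 0.25 and 0.26) and lost their call without AAV-TKT replicate 2 (median 0.073, adjusted p = 0.104). Autophagy and lysosome genes (median 0.062, adjusted p = 0.0474, and adjusted p = 0.449 with an estimated correlation) were led by Map1lc3a, Gabarapl1, Ctsd and Neu1 (0.25, 0.22, 0.17 and 0.16), and were lost without AAV-GFP replicate 1 or 3 or AAV-TKT replicate 2 or 3 (up to 0.232). They also lost their call in 7 of 13 other settings, with a median of -0.0044 under equal totals, where the median of all genes was -0.048.

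The other 17 lists besides the pentose phosphate pathway did not pass. Their median log2 changes were 0.11 for glycolysis, 0.066 for mitochondrial biogenesis and dynamics, 0.055 for purine and pyrimidine synthesis, 0.050 for NADPH, glutathione and antioxidant genes, 0.041 for cytoplasmic ribosomal proteins, -0.0017 for ribosome biogenesis, 0.0096 for mTOR and translation initiation, 0.031 for peptidergic nociceptor markers and -0.048 for pain ion channels. They were -0.11 for interferon response, 0.033 for heat shock and protein folding, -0.014 for the integrated stress and unfolded protein response, 0.023 for cholesterol biosynthesis, -0.046 for fatty acid synthesis, -0.013 for apoptosis and p53 targets, -0.018 for neurotrophins and growth factors and -0.078 for histone and chromatin modifiers. Within them, 4 genes passed adjusted over the list alone, namely Rrm2, the acid-sensing channel Asic3 (0.38) and the inducible heat shock proteins Hspa1a (-0.84) and Hspa1b (-0.86). T and B cell, endothelial, adipocyte and muscle, and central nervous system marker lists had 4, 4, 3 and 3 measured genes and were not tested.

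Among single genes ranked by unadjusted p and separated between the groups, none of the following passed. Higher values in AAV-TKT came from H1fx, a linker histone (14.1 ± 0.762 to 20.8 ± 1.72 FPKM, log2 change 0.53), the phosphatase Acp7 (0.67), the adrenergic receptor Adra1a (0.61), the transcription factor Mafa (0.53), the calcium buffer calretinin, Calb2 (1.19), Vstm2b (0.63), Yjefn3 (0.58), the matrix protein Comp (0.52) and Cyb5rl (0.69). Their adjusted p lay between 0.210 and 0.378. Lower values came from Lyz2 (-1.54) and Ngp (-2.63), each with a limma adjusted p = 0.0585, and from Chil3, a chitinase-like lectin of myeloid cells (-2.19), Ltf (-2.28), Lcn2 (-2.27), Il1b (-1.15), S100a9 (-2.52), Plaur (-0.76), the core histone gene Hist1h2bn (-1.73) and the antimicrobial peptide gene Camp (-2.12), with adjusted p up to 0.162. Lyz2 and Ngp did pass under some alternatives, such as a mean of at least 5 FPKM (limma adjusted p = 0.0226 each) and equal totals (0.0322 each). They did not with median-of-ratios scaling or quantile normalization. Gm24895, chosen after its values were seen, was at 12.3, 7.37 and 15.7 FPKM in AAV-GFP and was listed at 0 in all 3 AAV-TKT libraries (limma adjusted p = 0.0054). This gene of 74 bases lies on chromosome 12, from 109646129 to 109646202, inside an exon of the long noncoding RNA Rian on the same strand, so its reads cannot be told from those of Rian.

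In the limma test, 2 of 13178 genes passed a Benjamini-Hochberg threshold of 0.05, 1 higher and 1 lower, while 821 were higher and 574 lower at an unadjusted p under 0.05, where 659 in all would come by chance. Values of all 3 AAV-TKT libraries lay above or below all 3 AAV-GFP libraries for 18.5% of genes, against a chance share of 10%. Of 41 lists, 23 passed in camera with the preset correlation, 9 higher and 14 lower, and 0 passed with an estimated correlation (adjusted p of the 23 between 0.380 and 0.760). Calls past the threshold numbered 41 without AAV-GFP replicate 2, 4 without AAV-GFP replicate 3, 5 without AAV-TKT replicate 2, 23 with weights per library and 8 among protein-coding genes alone, an alternative chosen after seeing the data. Without AAV-GFP replicate 3, 13 lists passed, and 11 of the 23 lists passed whichever single library was left out.

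The ribose experiment asked how feeding the pathway with a pentose changes transcripts of ganglia at the same levels after the same injury. Over all genes, 1 passed, the processed pseudogene Gm15387, chosen here after its values were seen, which was listed at 0 in all 3 Vehicle libraries and stood at 24.2, 20.2 and 30.7 FPKM in the Ribose libraries (limma adjusted p = 8.5e-04). Its closest protein-coding match by sequence was Hmgb1, a chromatin protein that also acts as an alarm signal outside cells, and Hmgb1 was at 53.9 ± 2.72 FPKM in Vehicle and 27.9 ± 4.55 FPKM in Ribose (SD, n = 3 each; log2 change -0.94, adjusted p = 0.396). As lists, cytoplasmic ribosomal proteins and the nuclear genes of oxidative phosphorylation were lower in Ribose, each by a median of -0.16 on the log2 scale, but neither passed with an estimated correlation (adjusted p = 0.920 for each). Tkt did not pass the test, at 118 ± 7.18 FPKM in Vehicle and 108 ± 3.73 FPKM in Ribose.

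Gm15387 (ENSMUSG00000082585) lies on chromosome 15, from 74093686 to 74094333 on the minus strand, within no other annotated gene, and 96.6% of its 31-base words occur in transcripts of Hmgb1. Hmgb1 (ENSMUSG00000066551) lies on chromosome 5, from 149046702 to 149184489 on the minus strand. Reads of such near-identical copies may be assigned to either, so both values are uncertain. The annotated exons cover 648 bases in Gm15387 and 5023 in Hmgb1. On these lengths the same FPKM change stands for fewer reads in Gm15387. Reads moved to it would then cover only part of the fall of Hmgb1. The length of the expressed transcripts was not measured. The processed pseudogene Rpl38-ps2 was at 2.14 ± 2.79 and 34.2 ± 15.1 FPKM in Vehicle and Ribose, and its parent Rpl38, a ribosomal protein whose transcripts hold 100% of its 31-base words, at 155 ± 14.4 and 95.8 ± 5.36 FPKM. H3f3a-ps2, whose closest match is the histone gene H3f3a, was at 0.323 ± 0.131 and 5.65 ± 2.29 FPKM, and H3f3a did not go the opposite way (61.1 and 67.8 FPKM).

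**Figure D3:**
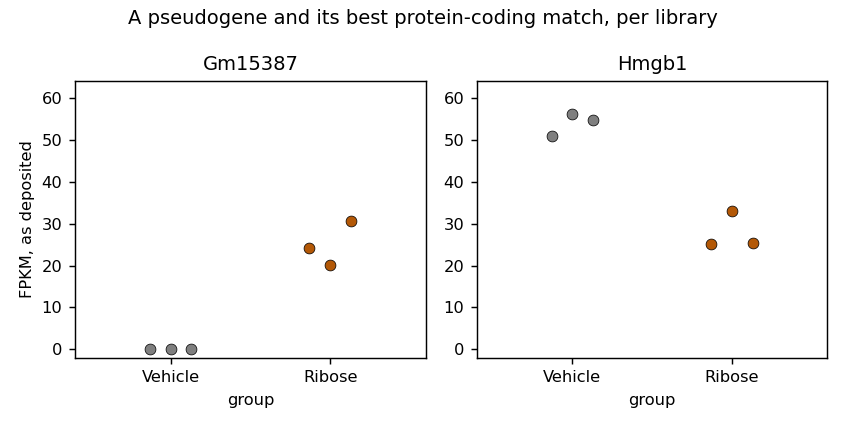
Level in FPKM, as deposited (vertical axis), of the processed pseudogene Gm15387 and of Hmgb1, its closest protein-coding match, for each library (points) of Vehicle and Ribose. Gm15387 was listed at 0 in each Vehicle library and lay between 20.2 and 30.7 FPKM in Ribose, where Hmgb1 averaged 27.9 FPKM against 53.9 FPKM in Vehicle. Annotated exons cover 648 bases in Gm15387 and 5023 in Hmgb1, so equal FPKM changes stand for unequal numbers of reads.

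Other separated genes with a small unadjusted p did not pass (adjusted p between 0.324 and 0.766). Higher values in Ribose came from Vcan, the matrix proteoglycan versican (1.02 ± 0.0938 to 4.77 ± 0.356 FPKM), Thoc2 of the mRNA export complex (6.04 ± 0.790 to 12.8 ± 1.91), the transcription factors Sp3 (13.5 ± 0.979 to 22.8 ± 1.81) and Mybl1 (2.36 ± 0.421 to 5.95 ± 0.694), the small nucleolar RNA Snora74a (log2 change 2.71), the keratin-associated protein gene Krtap1-4 (1.75), the pseudogene AW822252 (2.15) and the noncoding RNA AI427809 (1.36). Lower values came from Rsph3a, a radial spoke protein of cilia (30.0 ± 0.464 to 13.7 ± 2.79 FPKM), Gas5, a noncoding RNA that hosts small nucleolar RNAs (15.2 ± 0.0944 to 4.52 ± 2.90), Rps27l (25.0 ± 6.43 to 11.4 ± 2.23), Cyb5d1 (-0.62), Mettl26 (-0.60), the trafficking factor Trappc13 (-0.57), the adaptor Gab1 (-0.83) and neurotensin, Nts (-1.26). With Hmgb1 (-0.94), Rpl38 (-0.69), H3f3a-ps2 (2.28) and Rpl38-ps2 (3.77), these are the genes that the naming rule gave for each direction.

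Ribosomal protein genes and the nuclear genes of oxidative phosphorylation were lower as lists in Ribose, while other energy lists did not pass. Of 76 cytoplasmic ribosomal proteins, 69 were negative (median -0.16, camera adjusted p = 2.2e-10, and adjusted p = 0.920 with an estimated correlation). Rpl38 was the only call adjusted over the list alone and 0 passed over all genes, with Rps20 at 95.6 ± 9.10 and 57.8 ± 13.8 FPKM, Rps28 at 72.5 ± 6.23 and 54.9 ± 2.66, and Rpl11 at 146 ± 9.25 and 117 ± 5.20. The processed pseudogene Gm4332, chosen after its values were seen, shares 90.2% of its 31-base words with Rps20 and was at 39.4 ± 8.56 and 81.7 ± 10.0 FPKM, so the value of Rps20 is uncertain too. Of 71 nuclear oxidative phosphorylation genes, 66 were negative (median -0.16, adjusted p = 1.4e-09, and adjusted p = 0.920 with an estimated correlation), led by the complex I subunits Ndufs5 (-0.44) and Ndufs4 (-0.50) and the cytochrome c oxidase subunits Cox6c (-0.45) and Cox5b (-0.31). Mitochondrial ribosomal proteins (median -0.13, adjusted p = 0.0022) were led by Mrpl36, Mrpl4, Mrps9 and Mrpl22 (-0.61, -0.50, -0.44 and -0.54). Proteasome subunits had a median of -0.10 (adjusted p = 0.0027), and so did autophagy and lysosome genes (adjusted p = 0.0170). The adjusted p = 0.920 with an estimated correlation for each of these 3 lists too. The first pair of lists passed whichever single library was left out, and their medians moved both ways. They lay between -0.20 and -0.11 for cytoplasmic ribosomal proteins and between -0.23 and -0.066 for oxidative phosphorylation. Without Vehicle replicate 3 the oxidative phosphorylation median was -0.066, and with quantile normalization the ribosomal and oxidative phosphorylation medians were -0.075 and -0.10. Mitochondrial ribosomal proteins and the proteasome lost their calls without Vehicle replicate 3 (medians -0.075 and -0.048, adjusted p = 0.0594 and 0.171), and autophagy genes lost theirs without Vehicle replicate 2 or Ribose replicate 1 or 3 (up to 0.188), with a median of -0.058 without Vehicle replicate 2. The mitochondrial ribosomal median was -0.082 without Ribose replicate 3.

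Cell type markers varied within each group in the ribose experiment. Vehicle replicate 2 was at -0.34 for satellite glia (others 0.45 and 0.78), -0.72 for large-diameter neurons (0.26 and 0.39) and 0.84 for non-peptidergic nociceptors (-0.14 and -0.47). All 17 satellite glia markers were negative (median -0.68, camera adjusted p = 0.00174, and adjusted p = 0.920 with an estimated correlation), among them the lipid carrier Apoe (671 ± 289 and 379 ± 232 FPKM), the fatty acid binding protein Fabp7 (226 ± 106 and 123 ± 79.6), Ttyh1 (37.6 ± 15.0 and 19.5 ± 12.0) and Cdh19 (10.0 ± 4.18 and 5.87 ± 2.57), whose ranges overlapped between the groups. Ribose replicate 2 had a satellite glia score of -1.28, while the other Ribose libraries were at 0.24 and 0.14, and it was lowest of its group for Schwann, macrophage, endothelial, fibroblast and erythrocyte scores also. Without Vehicle replicate 3 or Ribose replicate 2 the satellite glia list lost its call (medians -0.40 and -0.087, adjusted p up to 0.563). Schwann cell and myelin markers (median -0.27, adjusted p = 0.00688, and adjusted p = 0.920 with an estimated correlation) included Mal (-0.75), Cnp (-0.31) and Cadm4 (-0.37), and were lost without Vehicle replicate 1 or 3 or Ribose replicate 2 (up to 0.611, median -0.060 without the last). The 6 measured adipocyte and muscle markers had a positive median of 0.49 (adjusted p = 0.0381, and adjusted p = 0.920 with an estimated correlation), with the muscle genes Tnni2 (1.11), Acta1 (1.45) and Myh2 (0.89) positive and Car3 at -0.21. This call was lost without Vehicle replicate 2 or Ribose replicate 1 or 2 (medians 0.27, 0.070 and 0.18, adjusted p up to 0.729). It was also lost in 6 of 13 other settings, among them no filter, median-of-ratios scaling, quantile normalization and weights per library. Endothelial and mural markers did not pass (median -0.29), nor did neutrophil (-0.16), erythrocyte (0.012) or macrophage markers (-0.35). Neuron lists did not pass either, with medians of -0.16 for non-peptidergic and 0.14 for peptidergic nociceptors, 0.040 for large-diameter neurons, -0.040 for pain ion channels and -0.027 for pan-neuronal genes.

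**Figure D4:**
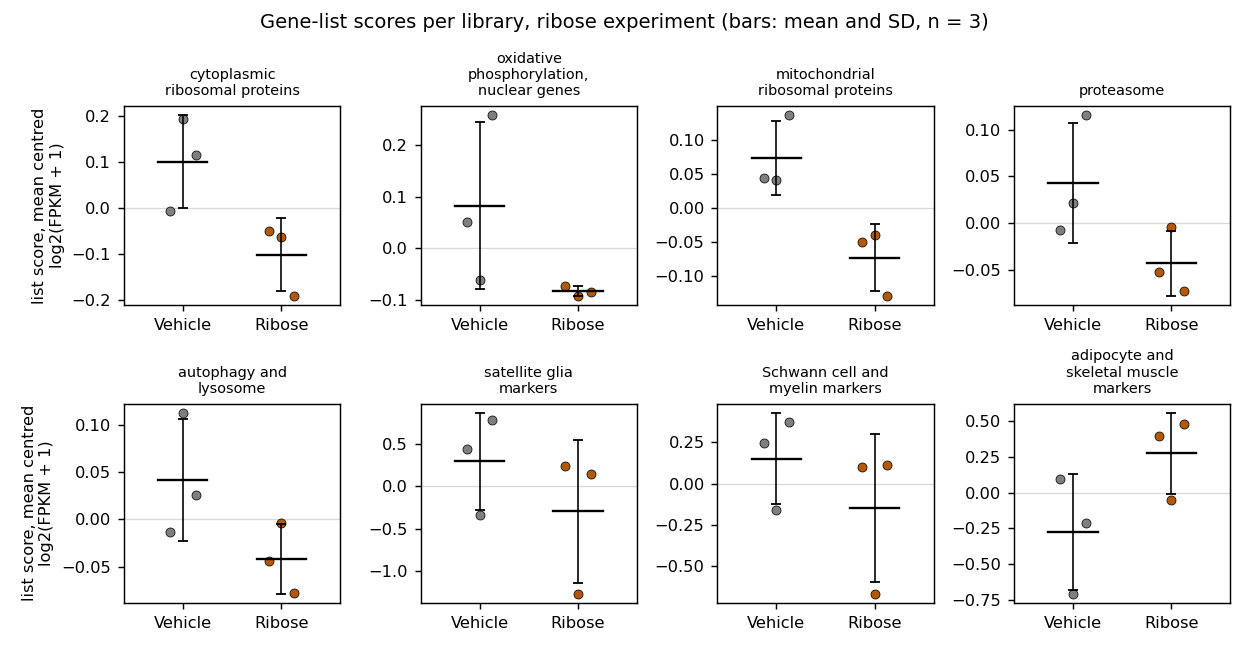
List scores, the mean over a list's measured genes of the centred log2(FPKM + 1) (vertical axes, each with its own range), for each library (points) of Vehicle and Ribose, with the mean and SD of 3 libraries. Cytoplasmic ribosomal protein scores averaged 0.10 in Vehicle and -0.10 in Ribose, and Ribose replicate 2, the middle point, lay at -1.28 in the satellite glia panel.

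No member of the pentose phosphate pathway list passed in Ribose (12 measured, median -0.078, camera adjusted p = 0.479; 0 calls over all genes and 0 adjusted over the list alone). Tkt had a log2 change of -0.13 (SE 0.0931, limma adjusted p = 1.00), lower in all 3 Ribose libraries, with an exact permutation p of 0.1, the smallest possible. Taldo1 was at 82.8 ± 6.67 and 72.5 ± 6.08 FPKM, Shpk at 3.27 ± 1.12 and 2.15 ± 0.847, Rpe at 16.8 ± 2.38 and 20.4 ± 4.11, and Rpia at 3.54 ± 0.422 and 2.77 ± 1.36 in Vehicle and Ribose. Log2 changes were 0.05 for G6pdx, -0.15 for Pgls, 0.02 for Pgd, 0.07 for H6pd, 0.08 for Rbks, -0.11 for Prps1 and -0.04 for Prps2. Glycolysis (median -0.050), the tricarboxylic acid cycle (-0.062), fatty acid oxidation (-0.080), mitochondrially encoded genes (-0.25, camera adjusted p = 0.0823), ribosome biogenesis (-0.081), regeneration-associated genes (-0.078) and axon growth genes (-0.055) did not pass either. Of 30 regeneration-associated genes, 25 were negative, as many as in AAV-TKT. The difference between the experiments did not pass for this list (camera adjusted p = 0.133). Among members of the glycolysis, tricarboxylic acid cycle, regeneration and axon growth lists with the smallest p were the glucose transporter Slc2a1 (-0.28), citrate synthase Cs (-0.13), the growth factor gene Bdnf (-0.45) and the adhesion molecule Ncam1 (-0.27).

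In the limma test, 1 of 13804 genes passed, and 386 were higher and 275 lower at an unadjusted p under 0.05, where 690 in all would come by chance. Groups were separated for 9.63% of genes, against a chance share of 10%. Of 43 lists, 8 passed in camera with the preset correlation, 1 higher and 7 lower, and 0 passed with an estimated correlation or in fry. T and B cell and central nervous system markers, with 2 and 3 measured genes, were not tested. Calls numbered 2 without Vehicle replicate 2, 2 without Vehicle replicate 3, 4 without Ribose replicate 2, 3 without Ribose replicate 3, and 0 among protein-coding genes alone. With Vehicle replicate 2 and Ribose replicate 2, the libraries lowest in satellite glia transcripts of their groups, both left out, an alternative chosen after seeing the data, 6 genes and 12 lists passed.

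Setting the 2 experiments side by side asked whether more transketolase and more ribose move the same transcripts. Each effect was computed within its own table, since how the tables were normalized is not stated. Tkt was the 1 gene of 12853 whose effect differed (1.27 in AAV-TKT and -0.13 in Ribose, difference 1.40, SE 0.119, limma adjusted p = 0.00114), with 543 genes higher and 337 lower at an unadjusted p under 0.05. The genes next in line did not pass. Differences toward AAV-TKT were 1.01 for Rpl38, 0.91 for Hmgb1, 1.15 for the zinc finger gene Zfp94 and 1.15 for Rsph3a, and differences toward Ribose were -2.08 for Thbs1, the matrix protein thrombospondin, -0.90 for Sp3, -0.90 for Nfkbia, -2.01 for Hist1h2bn and -1.06 for Hspa1b, with adjusted p between 0.176 and 0.240. Counts of genes whose effect differed were 3 without Vehicle replicate 3, 3 without Ribose replicate 2 and 2 without Ribose replicate 3.

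Of 41 lists, 12 differed between the experiments in camera, and 0 with an estimated correlation (lowest adjusted p = 0.511). Neutrophil (-1.83), red-cell (-1.18), immediate early (-0.24) and histone and chromatin genes (-0.12) were lower in AAV-TKT relative to the ribose effect. Oxidative phosphorylation (0.27), cytoplasmic (0.21) and mitochondrial (0.19) ribosomal proteins, proteasome (0.20), tricarboxylic acid cycle (0.18), axon growth (0.17), fatty acid oxidation (0.15) and autophagy genes (0.13) were higher. Across 12853 genes, which are not independent replicates, the effects had a Pearson r of 0.021 (p = 0.76 from 400 joint relabellings of the libraries) and a Spearman rho of 0.011 (p = 0.89), and 48.1% of genes had the same sign. Genes at an unadjusted p under 0.05 overlapped by 9 of 806 and 219 higher genes, where independent lists give 13.7, and by 13 of 530 and 269 lower genes, where independent lists give 11.1. Without AAV-GFP replicate 1, Vehicle replicate 2 or Ribose replicate 2 the r turned to -0.020, -0.028 and -0.046.

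**Figure D5:**
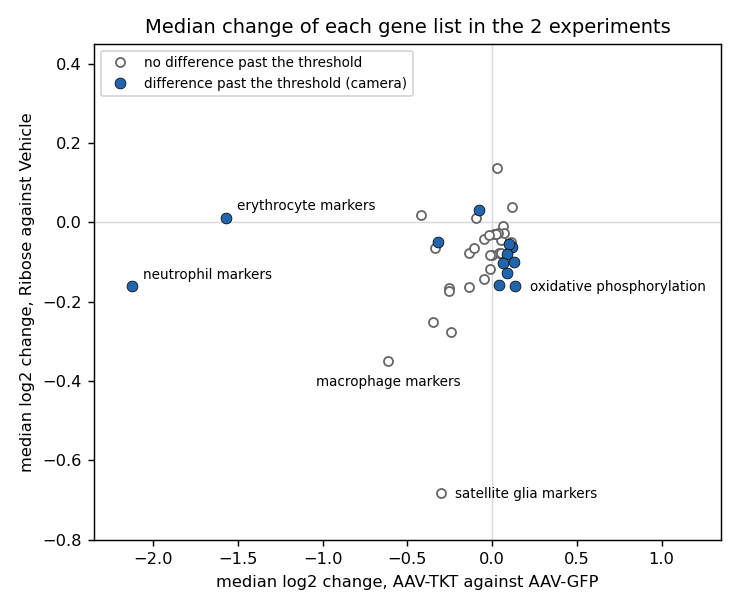
Median log2 change of each gene list in AAV-TKT against AAV-GFP (horizontal axis) and in Ribose against Vehicle (vertical axis), 1 point per list, filled where the effects differed in camera with the preset correlation. The neutrophil list lies farthest left, at -2.12 and -0.16, and the satellite glia list lowest, at -0.30 and -0.68.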

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

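The test of the difference between experiments and the regroupings of libraries were planned, and the 6 tests of explanations for the 3 patterns below were chosen after the results were seen. A test of the difference between the effects in the 2 experiments singled out Tkt (1.27 in AAV-TKT and -0.13 in Ribose, difference 1.40) and, in camera with the preset correlation, 12 gene lists, of which 0 passed with an estimated correlation (lowest adjusted p = 0.511). Medians of the difference were 0.27 for oxidative phosphorylation, 0.21 for cytoplasmic ribosomal proteins, 0.20 for proteasome, 0.19 for mitochondrial ribosomal proteins, 0.18 for the tricarboxylic acid cycle, 0.17 for axon growth, 0.15 for fatty acid oxidation and 0.13 for autophagy. They were -1.83 for neutrophil, -1.18 for erythrocyte, -0.24 for immediate early and -0.12 for histone and chromatin genes. Of 100 regroupings drawn from 200 possible, 33 gave at least as many differing genes as the real 1 (highest other 4), and 30 at least as many lists as the real 12 (highest other 23), so chance was not excluded for either count.

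Within each experiment the 10 splits of 6 libraries are too few for a share under 0.05. In the AAV experiment, 5 of 10 splits, the real one included, gave at least the real 2 genes (highest other 2), and 1 of 10 gave the real 23 lists (highest other 17). In the ribose experiment, 5 of 10 gave at least the real 1 gene (highest other 2), and 6 of 10 at least the real 8 lists (highest other 15).

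The first pattern weighed was the lower neutrophil and red-cell transcripts in AAV-TKT. Fewer immune cells with no other change would leave the red-cell markers where they were. The mean log2 difference of the 4 globin genes was -1.75 (SE 0.664), and 7 of 9 red-cell markers were lower in every AAV-TKT library. These values argue against that explanation for the red-cell markers, although that list did not pass with an estimated correlation. They are part of the pattern itself and no separate test. For the neutrophil markers the explanation stays open. A candidate explanation is that the amount of blood or marrow cells in the tissue differed between libraries, since within groups the neutrophil and globin scores moved together over 12 libraries (Pearson r = 0.904, permutation p = 0.00849), and the neutrophil minus globin difference was -0.19 (SE 0.360). The 3 AAV-TKT libraries, with low scores that varied little, were an exception (r = -0.428), and the pooled r rests on the AAV-GFP, Vehicle and Ribose groups (0.980, 0.996 and 0.972). The most abundant genes of the lists, Hba-a2 and Ngp, went from 125 to 33.0 and from 46.2 to 6.40 FPKM, no member of either list is in another list, and no sort or perfusion that would remove blood is stated in the labels; neither whether ganglion cells express these genes nor an effect of transketolase on recruitment of these cells, which the design also allows, was tested.

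The second pattern was the lower ribosomal protein and respiratory chain lists in Ribose. With a trend in annotated exon length removed, the lists kept at least 80.2% of their median change and passed in camera with the preset correlation. This argues against that trend as the whole cause. The length joined all annotated exons of a gene (medians 1805.5 and 1718 bases), and the length of the expressed transcripts was not measured. A trend with transcript length therefore stays open. Before this correction each list had adjusted p = 0.920 with an estimated correlation. With protein-coding genes alone as well, the medians of -0.16 and -0.16 became -0.091 and -0.082. Reads moved from parent genes to processed pseudogenes could account for part of it. The summed FPKM of 1236 processed pseudogenes rose by 693 (SE 304), and that of the lists changed by -1989 (SE 610). The ratio was 0.348, with a wide spread. FPKM is scaled to transcript length, so a read moved between copies of unequal length changes their values by unequal amounts. The pseudogene sum was also not limited to copies of genes in the lists. The ratio therefore does not measure the share of reads moved, and the question stays open. An effect of ribose stays open and untested.

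The third pattern was processed pseudogenes that were higher in Ribose while their protein-coding matches were lower, as in Gm15387 with Hmgb1. Reads of near-identical copies may have been assigned differently in the libraries of the 2 groups. With annotated exons of 648 and 5023 bases, reads moved to Gm15387 would cover only part of the fall of Hmgb1. Of 26 matched pseudogenes with an unadjusted p under 0.01, 69.2% had the opposite sign to their match (18 of 26, exact binomial p = 0.0755), against 51.7% of the other 259, which cannot be told apart from an even split at this number. Of the 24 that were higher in Ribose, 18 had a lower match (median log2 change of the 24 matches -0.12), and of the 2 that were lower, 0 had a higher match. An opposite sign here thus mostly means a lower match. Matches that were lower for another reason would give it too, and 69 of 76 cytoplasmic ribosomal proteins were lower in Ribose. The share therefore cannot decide whether reads were exchanged between copies. The relative depth also differed between these groups, and a biological cause was not tested.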

How the results depend on the processing

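Protein-coding genes alone, the length correction and the joint omission of Vehicle replicate 2 and Ribose replicate 2 were chosen after seeing the data; the other alternatives were planned. Tkt stayed higher in AAV-TKT under every alternative run, at 1.23 to 1.34 with 1 library left out (adjusted p 0.0102 to 0.0475). It missed the threshold only with the replicate number as a block (1.27, adjusted p = 0.0729), where 0 genes passed in limma. Fewer residual degrees of freedom are part of that setting. Same-numbered AAV libraries did not pair, since their deviations from the group means correlated at 0.033, 0.071 and -0.014 for replicates 1, 2 and 3. In the ribose experiment these correlations were 0.042, 0.357 and 0.16. The 2 AAV genes became 5 with a pseudocount of 0.1, 4 with a mean of at least 5 FPKM, 4 with equal totals, 23 with weights per library, 8 for protein-coding genes alone, 4 with the length trend removed, 11 with both, and 3 to 41 with 1 library left out, the highest without AAV-GFP replicate 2. The 1 ribose gene became 2 with a pseudocount of 0.5, 2 with equal totals, 0 for protein-coding genes alone, since Gm15387 is then not tested, 2 with the length trend removed, 0 with both, 1 to 4 with 1 library left out, the highest without Ribose replicate 2, and 6 in the joint omission. The 23 AAV lists became 0 with an estimated correlation, 1 in fry, 15 with quantile normalization and 13 to 25 with 1 library left out, the lowest without AAV-GFP replicate 3. The 8 ribose lists became 0 with an estimated correlation, 0 in fry, 6 to 12 with 1 library left out and 12 in the joint omission; 2 of the 8 passed whichever library was left out, and 4 were lost without Vehicle replicate 3. With all libraries kept, 13 of the 23 AAV lists and 4 of the 8 ribose lists passed in camera at the preset correlation under every alternative. In the AAV experiment, quantile normalization ended the calls of 9 lists that passed, among them the tricarboxylic acid cycle (0.117), axon growth (0.917) and proteasome (0.0562). Equal totals brought the median of pan-neuronal genes to 0.0010 (camera adjusted p = 0.0663) and of mitochondrial ribosomal proteins to 0.018 (adjusted p = 0.0112). That setting also moved the median of all genes from 0.014 to -0.048, so the smaller list medians partly reflect a shift of every gene. In the ribose experiment, quantile normalization ended the proteasome (0.462), autophagy (0.424) and adipocyte and muscle calls (0.116). The 1 gene differing between experiments became 2 with a pseudocount of 0.1, 1 to 3 with 1 library left out and 12 in the joint omission, and the 12 differing lists became 0 with an estimated correlation, 8 to 16 with 1 library left out and 19 in the joint omission. The correlation of effects (0.021) changed sign with a mean of at least 5 FPKM (-0.014) and in the joint omission (-0.090), and lay between -0.046 and 0.075 with 1 library left out. Mitochondrially encoded genes in AAV-TKT had a median of -0.57 to 0.029 with 1 library left out, the sign turning without AAV-TKT replicate 2. Except where stated, the cause was not tested. Removing the filter left the AAV table as it was, because it lists no gene with a mean under 1 FPKM, and read depth, unknown in the AAV table, limits what low values show.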
